A study of Homo sapiens with 12 samples.

How the data were processed

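RNA from HCT-116 cells, a human colorectal carcinoma line, was sequenced in 12 libraries that the sample titles place in 4 groups of 3: untreated cells, cells given CPT-11 (irinotecan) for 24 h, cells pretreated with lovastatin for 4 h before CPT-11, and cells with SHP2 silenced by short hairpin RNA and given CPT-11. The treatment label of the SHP2-silenced samples also mentions lovastatin, whereas their titles and the treatment protocol do not. These samples were grouped by title, and the conflict is stated beside the results it touches. Total RNA was extracted with Trizol and made into libraries with a NEBNext Ultra kit, per the labels' protocols. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

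A single deposited table gives FPKM values (reads per gene, divided by gene length and a library factor) for 59172 features in the 12 libraries. The submitters' processing notes name HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.16.1, and the genome build hg19. The coordinates in the table disagree with that build: all 58735 features with an Ensembl identifier carry the chromosome, start and end of GENCODE release 29 (Ensembl 94), which is on GRCh38 (100% identical). The other 437 features have identifiers given by the submitters. Coordinates are given as GRCh38. The options used for strand, multiply mapped reads and overlapping genes are not given in the sources used here, so reads of near-identical copies, of overlapping genes and of antisense partners cannot be told apart.

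Each FPKM value multiplied by the gene's deposited length was a whole multiple of 1 step per library. This held for 100% of nonzero values within 0.01 of a whole read, with a largest gap of 6.984e-05. The steps gave 14447847 to 16224271 reads assigned to genes per library. The scaling behind the deposited FPKM was not the total of assigned reads, from which it departed by factors of 0.977 to 1.06. It was proportional to median-of-ratios size factors within factors of 0.999 to 1.00 of their mean ratio. A change therefore is relative to the typical gene and cannot show a shift of all genes together.

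The tests planned before the data were examined assumed read counts and a test that models them. The table held FPKM, so limma (version 3.58.1, R 4.3.3) was used instead on log2(FPKM + 1), with a trend of the variance over mean expression. The whole reads recovered from the FPKM values were tested only with voom, which was chosen after the data were seen. No other test on counts was run, nor were the other alternatives that need one. Fold changes are on the log2(FPKM + 1) scale, which understates the changes of genes with low values. All 12 libraries entered 1 model with a mean per group, so that the groups share an estimate of the spread. The groups were not equal in spread. The root mean square log2 difference of a library to the others of its group was 0.206 to 0.330 for CPT-11 and 0.152 to 0.170 for silenced cells. A shared estimate may therefore understate the error in comparisons with CPT-11. A gene was tested if it had at least 10 reads, scaled to the median library, in at least 3 libraries and at least 15 reads in total. This left 18062 genes, of which 13743 were protein-coding. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, at a threshold of 0.05.

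Gene lists were fixed before the data were examined. There were 22, on DNA damage signalling, DNA repair, the cell cycle, innate immunity, sterol and fatty acid synthesis, ERK and YAP targets, stress responses, cell death, CPT-11 handling and cell identity. Each was tested in the 4 comparisons with limma's camera at its preset correlation of 0.01, and p-values were adjusted over the 88 tests. Each test was repeated with a correlation estimated from the data. Members that passed the gene test were counted after adjustment over all genes and adjusted over the list alone. The genes named in the text follow a rule fixed at the same time: PTPN11, the 8 largest rises and 8 largest falls among protein-coding genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups, at most 3 members of each list with the smallest p, and a fixed set for innate immunity, CPT-11 response and sterol synthesis. Genes named outside this rule are said to have been chosen after their values were seen. Some genes that meet the rule are not named because they are withheld for evaluation.

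The gene test was tested on simulated reads for CPT-11 against untreated cells. Reads were drawn for all features, and 17746 genes passed the filter. The test recovered 54 of 66 genes changed 1.5-fold (81.8%), 62 of 67 changed 2-fold (92.5%) and 64 of 65 changed 4-fold (98.5%). Of 187 calls, 7 were false (3.74%), and 0 genes were called between unchanged groups. Reads were drawn independently, with the same dispersion for all genes (0.00397) and no deviation common to a library, and genes with low values were not changed. These shares therefore do not measure false calls in the real data, where a library such as CPT-11 replicate 3 deviated as a whole. The list test called 0 of 200 unchanged lists and called a list shifted by 0.3. These were random lists of independently drawn genes, so their members were uncorrelated. In the data the estimated correlation was 0.24 for mitosis and 0.31 for mitochondrially encoded mRNAs, which this check does not cover.

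Alternatives chosen before the data were examined were no filter on low counts, a filter of at least 1 CPM, a fit of only the groups compared, the replicate number as a block, a pseudocount of 0.1, a further minimum of 2-fold, scaling without the 20 most counted genes, and leaving out each library in turn. Alternatives chosen after seeing the data were voom on the recovered reads, scaling to library totals or by a trimmed mean of M-values, and the removal of each library's smooth trend over GC content and then gene length. The last was also run without CPT-11 replicate 3, a library that stood apart from its group. GC content was taken from the reference transcripts and was known for 98.5% of the tested genes.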

Results

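The series asks how DNA damage by chemotherapy bears on the cGAS-STING pathway, in which the enzyme cGAS senses cytosolic DNA and signals through STING to interferon. HCT-116 colon cancer cells were left untreated, given CPT-11 (irinotecan, whose active form traps topoisomerase I on DNA), given CPT-11 after lovastatin (an inhibitor of HMG-CoA reductase), or given CPT-11 with SHP2 silenced. Each group had 3 libraries of 14447847 to 16224271 assigned reads. Gene values are means in FPKM ± SD of 3 libraries, and fold changes are log2 differences ± SE from limma with Benjamini-Hochberg adjusted p-values.

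PTPN11, which encodes the phosphatase SHP2 (ENSG00000179295, chromosome 12, 112418351 to 112509913), was low in the libraries labelled as silenced. It measured 6.01, 6.54 and 7.15 FPKM there, against 48.2, 50.5 and 43.9 with CPT-11 alone, 43.4, 43.2 and 45.4 with lovastatin and CPT-11, and 53.3, 53.8 and 55.4 in untreated cells. Silenced cells thus differed from CPT-11 alone by -2.68 ± 0.07 (adjusted p = 2.6e-09) and from the lovastatin group by -2.57 ± 0.07 (adjusted p = 4.2e-09). PTPN11 differed between CPT-11 and untreated cells by -0.19 ± 0.07, which did not pass (adjusted p = 0.075) but passed after a correction for GC content and gene length (adjusted p = 0.010). HMGCS1, a sterol synthesis gene (chromosome 5, 43289395 to 43313512), measured 101 to 105 FPKM in the lovastatin libraries, 24.9 to 25.8 in the SHP2-silenced libraries and 25.2 to 31.2 with CPT-11 alone. The lovastatin named in the treatment label of the silenced samples was therefore not seen in this gene.

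**Figure D1:**
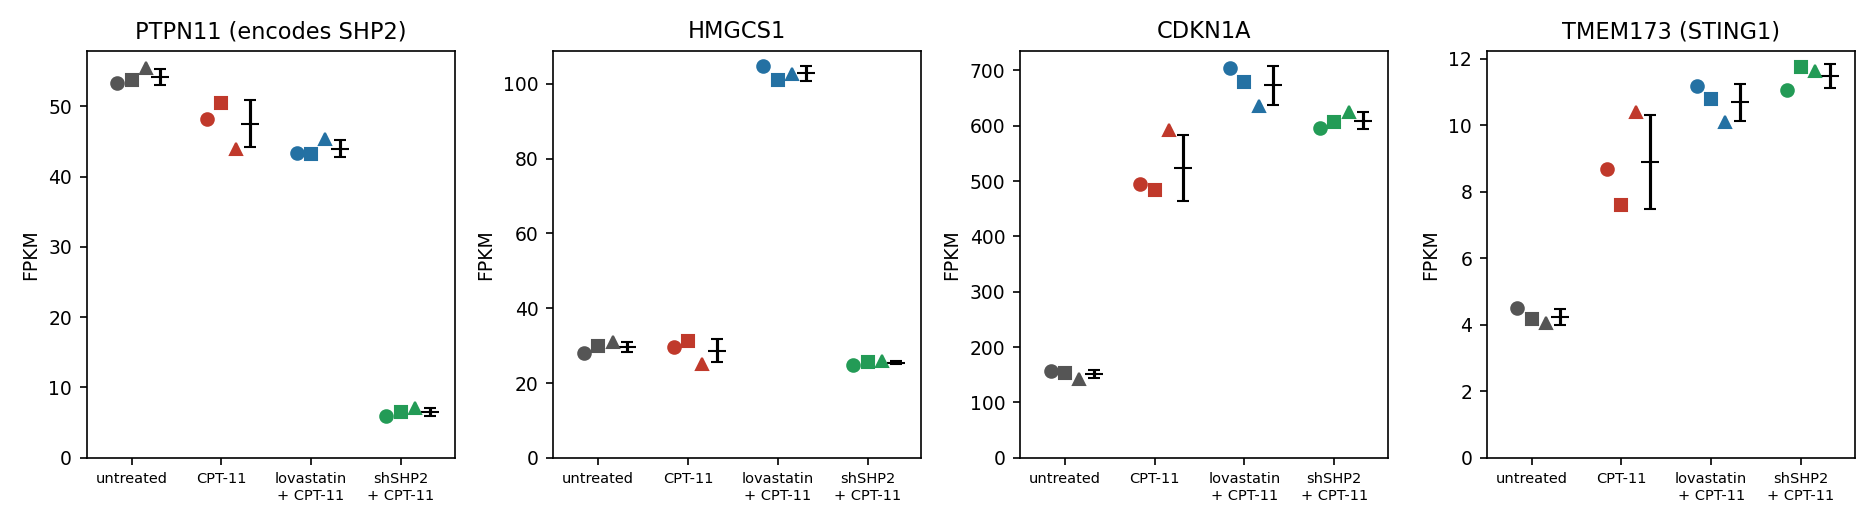
FPKM of PTPN11, HMGCS1, CDKN1A and TMEM173 in each library (circle, square and triangle are replicates 1, 2 and 3), with the mean and SD of the 3 libraries of each group beside them. PTPN11 lay at 6.01 to 7.15 in the SHP2-silenced group and HMGCS1 at 101 to 105 in the lovastatin group, apart from all other libraries.

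CPT-11 replicate 3 stood apart from the other CPT-11 libraries. Its values rose with GC content by 0.08 (log2 per 10 points of GC), against -0.16 and -0.18 in replicates 1 and 2. RN7SL2, a structural RNA of the signal recognition particle, measured 400 FPKM in it against 37.2 and 17.6, and FTH1, which encodes ferritin heavy chain, 422 against 106 and 73.9. Both genes were named after their values were seen. In GC slope and RN7SL2 the library lay nearer to the lovastatin libraries, with slopes of 0.01 to 0.08 and 227 to 346 FPKM of RN7SL2. Over all tested genes its log2 values correlated less with CPT-11 replicates 1 and 2 (Pearson r = 0.982 and 0.977) than with other treated groups. The r was 0.992 to 0.993 with lovastatin libraries and 0.990 to 0.991 with SHP2-silenced libraries. FTH1 did not place it with a single group, at 360 to 419 FPKM with lovastatin, 411 to 441 in SHP2-silenced and 191 to 413 in untreated libraries. Untreated replicate 1, with 413 FPKM of FTH1 against 235 and 191 in its group, deviated from its group in a similar way (correlation of the deviations with those of CPT-11 replicate 3, r = 0.44, the highest between libraries of different groups). GC slopes were 0.11 to 0.14 in SHP2-silenced and -0.15 to -0.01 in untreated libraries. RN7SL2 measured 1065 to 1469 FPKM in SHP2-silenced and 71.1 to 155 in untreated libraries. The labels give no batch, and counts against CPT-11 are given with and without this library.

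**Figure D2:**
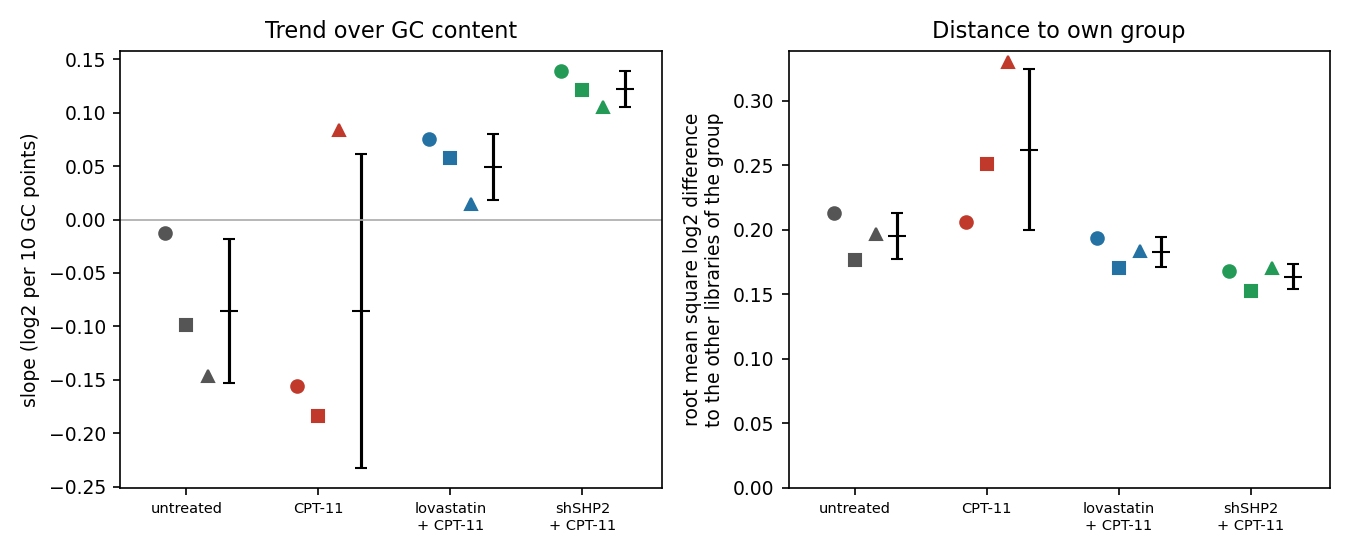
Left, slope of each library's log2 values over GC content (log2 per 10 GC points). Right, root mean square log2 difference of each library to the mean of the other libraries of its group; points are libraries (circle, square and triangle are replicates 1, 2 and 3), with the mean and SD of each group. CPT-11 replicate 3 had a slope of 0.08 and a difference of 0.330, against at most 0.213 in the other groups.

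CPT-11 was compared with untreated cells to show the response to the drug. Targets of the tumour suppressor p53 rose together: 35 of the 38 measured members rose and 1 fell, with a median log2 fold change of 1.04. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 151 ± 7.5 to 523 ± 60 FPKM, BTG2, an antiproliferative gene, from 21.7 ± 1.5 to 61.7 ± 3.4, and the phosphatase gene PPM1D from 12.2 ± 0.77 to 34.6 ± 2.6. KITLG, named after its values were seen, was the member that fell, by 0.97 (adjusted p = 9.3e-05). Adjusted over the list alone the counts were 36 and 1. The list passed its test (camera, adjusted p = 5.6e-39; adjusted p = 5.2e-05 with an estimated correlation).

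Of the 8 largest rises TP53I3, CD82 and TP53INP1 were members of the p53 list. TP53I3 rose from 5.20 ± 0.75 to 32.3 ± 7.1 FPKM (log2 change 2.41 ± 0.13, adjusted p = 6.1e-07), followed by PTAFR, the receptor of platelet-activating factor (2.31 ± 0.09), the cytokine subunit gene EBI3 (2.17 ± 0.10) and the adhesion genes NECTIN4 (2.07 ± 0.07) and CEACAM1 (2.06 ± 0.10). SERPINB5, a serpin gene, rose by 2.03 ± 0.05, CD82 by 1.94 ± 0.11 and TP53INP1 by 1.85 ± 0.06. VGF fell by 1.38 and the nuclear receptor gene NR2F1 by 1.35. H1FX and H2AFX, which encode histone variants, fell by 1.20 and 1.09, the transcription factor gene KLF2 by 1.10 and DHRS2 by 1.03. VGF, H1FX, KLF2 and H2AFX varied more between CPT-11 libraries than the others, for example 74.1 ± 28 FPKM for H2AFX against 152 ± 15 untreated.

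Interferon-stimulated genes rose with CPT-11 by small amounts. Of the 34 measured members 21 rose and 1 fell (25 and 1 adjusted over the list alone), with a median of 0.39. OAS3, an antiviral enzyme gene, rose from 13.9 ± 0.33 to 21.2 ± 0.30 FPKM, OASL from 11.1 ± 0.63 to 17.8 ± 0.69 and HERC5 from 10.1 ± 0.74 to 15.6 ± 1.2. IRF9, named after its values were seen, was the member that fell. The list passed its test (adjusted p = 7.7e-12; adjusted p = 0.019 with an estimated correlation). NF-kB targets and inflammatory cytokines also passed (adjusted p = 1.1e-03; adjusted p = 0.044 with an estimated correlation): 7 of 21 rose and none fell (10 and 1 adjusted over the list alone), among them CXCL8, from 2.83 ± 0.68 to 5.02 ± 0.79 FPKM, NFKB2 and TNFAIP2. Antigen presentation passed with 7 of 17 up (adjusted p = 2.8e-04), led by the peptide transporter gene TAP1, which rose by 0.97 ± 0.09, but not with an estimated correlation (adjusted p = 0.064). Reads of HLA genes may be split between near-identical copies.

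The components of the cGAS-STING pathway did not pass as a list (adjusted p = 0.35; median -0.01, mean 0.09, test direction up). Of 16 measured, 4 rose and BANF1, named after its values were seen, fell, with the same counts adjusted over the list alone. TMEM173, which encodes STING (chromosome 5, 139475534 to 139482935), rose from 4.24 ± 0.24 to 8.89 ± 1.4 FPKM (0.91 ± 0.09, adjusted p = 6.9e-05). The ubiquitin ligase gene TRIM32 rose by 0.39 ± 0.06 and NLRX1 by 0.53 ± 0.11. CGAS had 0 to 5 reads per library and was not tested, so its change was not detectable at this depth. IFNB1, which encodes interferon beta, had 1 read in each untreated library and 0, 9 and 4 with CPT-11, too few to test. TREX1 had 0 reads in all libraries, but it overlaps another gene in the annotation, and its reads may have been assigned elsewhere. CXCL10 (1.39 ± 0.13 against 0.871 ± 0.12 FPKM, adjusted p = 0.21) and CCL5 (1.80 ± 0.32 against 1.66 ± 0.51, adjusted p = 0.74) did not pass.

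Mitotic genes fell with CPT-11. Of 35 members 20 fell, and CDK1, named after its values were seen, rose (24 and 1 adjusted over the list alone), with a median of -0.38. CDC20, an activator of the anaphase-promoting complex, fell from 139 ± 11 to 60.9 ± 8.3 FPKM, the kinase gene PLK1 from 31.8 ± 0.71 to 14.9 ± 1.2 and the cyclin gene CCNB1 from 87.3 ± 4.1 to 55.5 ± 0.70. The list passed (adjusted p = 1.7e-12), but not with an estimated correlation (adjusted p = 0.090). Damage checkpoint genes fell in 6 of 21 (adjusted p = 0.016), led by CDC25B and MDC1, a call lost with an estimated correlation (adjusted p = 0.29) and without CPT-11 replicate 3 (adjusted p = 0.12). Replication and E2F targets went both ways, 6 up and 10 down of 37, and did not pass (adjusted p = 0.12). They passed narrowly downward with the GC and length correction (adjusted p = 0.0497), but not with it and without CPT-11 replicate 3 (adjusted p = 0.16). PCNA, the replication clamp, rose from 195 ± 6.9 to 379 ± 20 FPKM, whereas the helicase subunit genes MCM7 and MCM6 fell by 0.61 and 0.67.

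Cell death regulators passed (adjusted p = 3.1e-03; adjusted p = 0.044 with an estimated correlation). Of 24 members 7 rose and none fell, counts that were the same adjusted over the list alone. BIK, which encodes a death-promoting BCL2 family member, rose by 1.03 ± 0.07, and CFLAR, an inhibitor of caspase 8, and GSDME rose by 0.47 and 0.42. Fatty acid synthesis passed with 5 down and 1 up of 14 (adjusted p = 0.010; 0.069 as the adjusted p with an estimated correlation). YAP and TAZ targets passed with 7 up and 3 down of 22 (8 and 3 adjusted over the list alone; adjusted p = 0.042; adjusted p = 0.10 with an estimated correlation), a call also lost without CPT-11 replicate 2 or untreated replicate 3 (adjusted p = 0.059 and 0.069). Colon epithelial genes passed with 5 up and 1 down of 11 (adjusted p = 0.016; adjusted p = 0.22 with an estimated correlation; adjusted p = 0.060 without CPT-11 replicate 3). Markers of fibroblasts, endothelium and blood cells, a list for RNA of other cells, had 2 members up of 7 measured (adjusted p = 0.037; adjusted p = 0.26 with an estimated correlation; adjusted p = 0.090 without CPT-11 replicate 3). These were ACTA2, 2.39 ± 0.04 against 0.986 ± 0.11 FPKM, and ITGAM. In all 8 lists passed upward, and 6 did so without untreated replicate 3 or without CPT-11 replicate 3. There were 7 without CPT-11 replicate 1, with a filter of at least 1 CPM, with only these groups in the fit and with scaling to library totals.

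The remaining lists did not pass. Adjusted p was 0.91 for homologous recombination and Fanconi repair, 0.19 for end joining, PARP and single-strand break repair, 0.12 for histones, 0.28 for cholesterol synthesis and uptake, 0.54 for prenylated GTPases and KLF factors, 0.93 for ERK pathway targets, 0.11 for the integrated stress and unfolded protein response (0.043, downward, with the GC and length correction and without CPT-11 replicate 3), 0.29 for CPT-11 target and handling, and 0.18 for mitochondrially encoded mRNAs. CES2, a carboxylesterase that activates CPT-11, rose from 8.21 ± 0.25 to 16.4 ± 0.91 FPKM (adjusted p = 3.0e-06). TOP1, the drug's target, measured 100 ± 14 against 106 ± 5.7 FPKM (adjusted p = 0.58), and PARP1 64.8 ± 4.2 against 72.2 ± 1.1 (adjusted p = 0.063).

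In all, 2989 of 18062 genes differed between CPT-11 and untreated cells, 1598 higher and 1391 lower, of which 121 changed at least 2-fold (101 up, 20 down). The count was 1154 with only these groups in the fit, 1931 without untreated replicate 2 and 4420 without CPT-11 replicate 3. Of 76 calls of named genes 17 ended with only these groups in the fit, among them those of H1FX, NLRX1, CXCL8, NFKB2 and TNFAIP2. Scaling to library totals moved the split to 1910 higher and 1004 lower, and scaling without the 20 most counted genes to 1967 and 963.

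**Figure D3:**
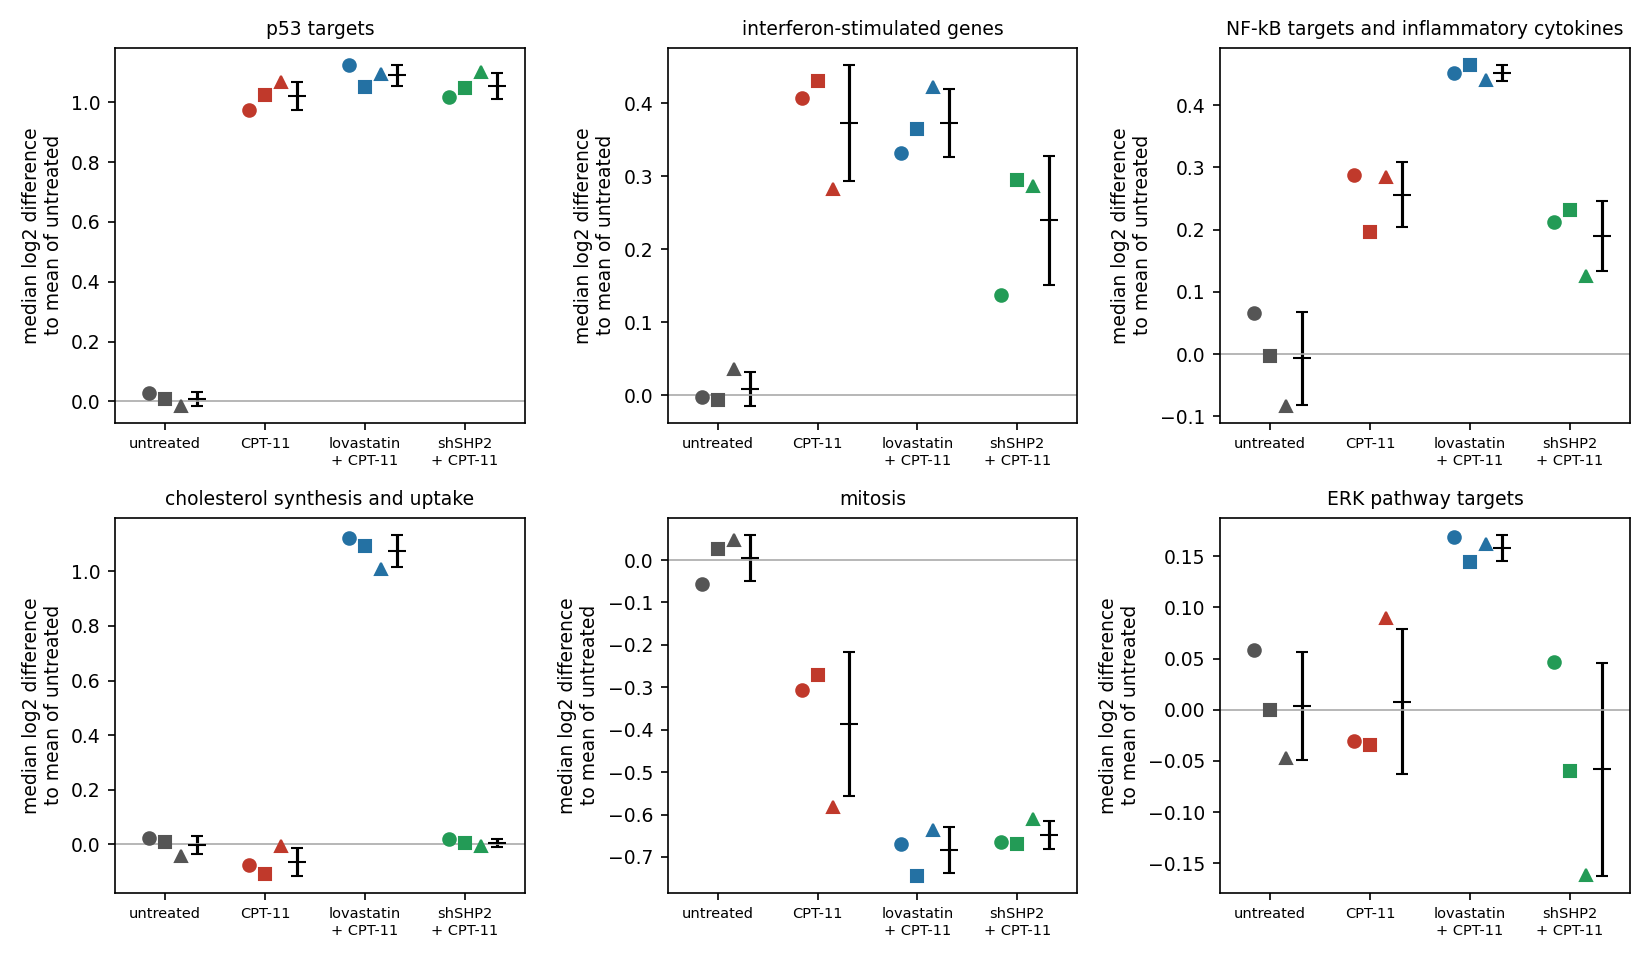
Median over the measured members of 6 gene lists of the log2 difference between a library and the mean of the untreated libraries, log2(FPKM + 1) scale; points are libraries (circle, square and triangle are replicates 1, 2 and 3), with the mean and SD of each group. The p53 list lay at 0.97 to 1.12 in all libraries given CPT-11, and the cholesterol list at 1.01 to 1.12 in the lovastatin libraries and at -0.11 to 0.02 in the others given CPT-11.

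Lovastatin pretreatment was compared with CPT-11 alone. No group received lovastatin without CPT-11, so whether the drugs interact cannot be tested. Cholesterol synthesis and uptake rose almost as a whole: 24 of 26 members rose and none fell, also adjusted over the list alone, with a median of 1.07 (adjusted p = 3.8e-51; adjusted p = 7.2e-05 with an estimated correlation). HMGCS1 rose from 28.7 ± 3.1 to 103 ± 2.0 FPKM (1.81 ± 0.07, adjusted p = 1.2e-07), INSIG1, a sterol sensor of the endoplasmic reticulum, from 12.6 ± 0.58 to 44.5 ± 0.40, and FDFT1, squalene synthase, from 31.3 ± 0.50 to 79.8 ± 4.6. The other largest rises were sterol synthesis genes as well, MVD by 1.65, LSS by 1.41, CYP51A1 by 1.41, MSMO1 by 1.36 and DHCR7 by 1.35. Fatty acid synthesis rose in 6 of 14 members (12 adjusted over the list alone; adjusted p = 1.1e-15; adjusted p = 4.4e-04 with an estimated correlation). SCD, the stearoyl-CoA desaturase, rose from 142 ± 2.8 to 328 ± 10 FPKM, ACSS2 from 12.9 ± 0.95 to 30.5 ± 0.58 and ACLY from 75.3 ± 2.1 to 110 ± 0.82.

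Cell cycle genes were lower as lists with lovastatin, although few members passed singly. Replication and E2F targets had a median of -0.18, with 2 of 37 down over all genes and 20 down and 1 up adjusted over the list alone (adjusted p = 3.1e-12; adjusted p = 0.038 with an estimated correlation). ORC1, of the origin recognition complex, fell from 17.7 ± 1.4 to 13.5 ± 0.45 FPKM. For mitosis 0 of 35 passed over all genes and 24 fell adjusted over the list alone (median -0.27, adjusted p = 1.1e-12; adjusted p = 0.090 with an estimated correlation). For homologous recombination and Fanconi repair these were 0 and 17 of 35 (median -0.22, adjusted p = 1.3e-07; adjusted p = 0.090 with an estimated correlation), and for damage checkpoint 0 and 5 of 21 (adjusted p = 2.0e-03; adjusted p = 0.22 with an estimated correlation). The mitosis medians of single libraries against untreated cells were -0.31 and -0.27 in CPT-11 replicates 1 and 2, -0.58 in replicate 3 and -0.74 to -0.64 with lovastatin. Those of homologous recombination and Fanconi repair were 0.07 and 0.09 in CPT-11 replicates 1 and 2, and -0.14 in replicate 3, inside the -0.19 to -0.10 with lovastatin. After the GC and length correction the median of this list was -0.14 and that of damage checkpoint -0.06 in place of -0.15, and both passed (adjusted p = 8.3e-08 and 7.9e-03). Among the largest falls, which were small, were ESCO2, a cohesin acetyltransferase gene (fell by 0.55), OR51B4 (fell by 0.43), PRKDC, PKP4, FAM81A, DTL and CDCA2 (fell by 0.38). The calls of these genes were each lost when any library of either group other than CPT-11 replicate 3 was left out, and with only these groups in the fit 36 genes were higher and 0 lower.

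NF-kB targets were higher with lovastatin, 1 of 21 up over all genes and 7 adjusted over the list alone (adjusted p = 2.8e-04; adjusted p = 0.038 with an estimated correlation). CXCL3 rose from 0.335 ± 0.11 to 1.06 ± 0.14 FPKM. Histones passed with a median of 0.45, 1 of 9 up over all genes and 5 up and 1 down adjusted over the list alone (adjusted p = 1.8e-03; adjusted p = 0.044 with an estimated correlation), but not without CPT-11 replicate 3 (adjusted p = 0.065). HIST1H2AC rose from 2.87 ± 0.21 to 4.76 ± 0.71 FPKM, and histone genes are near-identical copies whose reads may be split. The list was of 21 replication-dependent histone genes, and those beyond the 9 had too few reads to test. It therefore does not show histone mRNA as a whole. ERK pathway targets (1 of 26 up, 4 adjusted over the list alone, adjusted p = 2.0e-03) and the stress response (2 of 24 up, 6 adjusted over the list alone, adjusted p = 4.3e-04) passed, with adjusted p = 0.26 and 0.090 with an estimated correlation. Members that rose were the immediate early gene IER2, by 0.67 ± 0.12, and the stress genes PPP1R15A and ATF3, by 0.44 ± 0.07 and 0.31 ± 0.06.

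Unlike the NF-kB list, the interferon-stimulated and cGAS-STING lists did not pass between lovastatin and CPT-11 alone. Interferon-stimulated genes had an adjusted p of 0.68 (median -0.04, mean 0.04, test direction up), with OASL up by 0.40 ± 0.06 as the member that passed over all genes. The cGAS-STING list had an adjusted p of 0.22 and 0 of 16 members past the test. TMEM173 measured 10.7 ± 0.56 against 8.89 ± 1.4 FPKM (adjusted p = 0.20), CXCL10 2.08 ± 0.53 against 1.39 ± 0.13 (adjusted p = 0.28) and CCL5 2.91 ± 0.52 against 1.80 ± 0.32 (adjusted p = 0.16). For p53 targets the adjusted p was 0.14, and CDKN1A measured 673 ± 34 against 523 ± 60 FPKM (adjusted p = 0.098). After the correction for GC content and length the p53 list and cell death regulators passed upward (adjusted p = 9.4e-03 and 0.030), and end joining, PARP and single-strand break repair downward (adjusted p = 0.0497). The ERK list, with a median of 0.13, then had 0.06 (adjusted p = 7.3e-03) and was lost when CPT-11 replicate 3 was also left out (adjusted p = 0.055). In that last setting 1 list was gained over the uncorrected tests, in place of the 3 gained with the correction alone.

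Between lovastatin and CPT-11 alone 84 genes differed, 71 higher and 13 lower, of which 17 rose and 0 fell at least 2-fold. Without CPT-11 replicate 3 the count was 5455, and without any other library of these groups it was 41 to 47. CPT-11 replicates 1 and 2 had GC slopes of -0.16 and -0.18, against 0.01 to 0.08 with lovastatin. Their RN7SL2 was 37.2 and 17.6 FPKM, against 227 to 346. Without replicate 3 library content thus ran with the treatment, and the 5455 cannot be assigned to lovastatin alone. Without a silenced library, which enters only through the shared spread, 50 to 56 genes were higher and 3 to 5 lower. With the GC and length correction the count was 335 (166 higher, 169 lower), and with it and without CPT-11 replicate 3 it was 3066. Of 27 calls of named genes 17 ended with only these groups in the fit, those of CYP51A1, OASL, CXCL3, ORC1, HIST1H2AC, IER2, PPP1R15A and ATF3 among them besides the falls, and 14 to 17 ended without any 1 library of these groups other than CPT-11 replicate 3.

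SHP2-silenced cells were compared with CPT-11 alone, with the titles taken as right. No untreated silenced cells and no control hairpin are labelled, so effects of silencing cannot be parted from those of the vector or of the derived cells. Beyond PTPN11, ADAM19, a membrane metalloprotease, fell from 21.9 ± 0.79 to 8.19 ± 0.83 FPKM (-1.32 ± 0.07, adjusted p = 4.9e-06), VCAN, a matrix proteoglycan, from 31.9 ± 5.7 to 13.7 ± 0.40 and DUSP6, a phosphatase that ERK signalling induces, from 46.7 ± 5.7 to 21.2 ± 0.83. EHF, FGF9, NRP1 and SLC16A6 fell by 1.17, 1.15, 1.14 and 1.13. MAGEB1 rose from 1.06 ± 0.24 to 5.36 ± 0.47 FPKM, ID3, an inhibitor of differentiation factors, from 15.3 ± 4.3 to 41.1 ± 0.49, and the epithelial surface gene PROM2 to 6.35 ± 0.55. TMEM238, MRPL12, RAC3 and TMEM141 rose by 1.35 to 1.55, but CPT-11 libraries differed widely in them (9.76 ± 9.7 FPKM for TMEM238). The call of TMEM238 ended with the GC and length correction, which took its change from 1.55 ± 0.47 to 0.85 ± 0.28 (adjusted p = 0.055); with that correction and without CPT-11 replicate 3 it passed (adjusted p = 4.2e-04).

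ERK pathway targets went both ways, 10 down and 5 up of 26 (11 and 5 adjusted over the list alone). DUSP6 fell as above, ETV1, a transcription factor downstream of ERK, from 6.37 ± 0.42 to 3.21 ± 0.19 FPKM, whereas MYC rose from 76.6 ± 3.0 to 121 ± 0.21. The list did not pass (adjusted p = 0.058; adjusted p = 0.42 with an estimated correlation), but passed downward with the GC and length correction (adjusted p = 1.2e-03) and without CPT-11 replicate 1 or 2 (adjusted p = 0.018 and 0.026) or silenced replicate 1 or 2 (adjusted p = 0.013 and 0.040). Mitosis fell in 20 of 35 and rose in BIRC5, named after its values were seen (23 and 2 adjusted over the list alone), with ANLN, a cytokinesis gene, from 36.4 ± 6.6 to 18.1 ± 0.06 FPKM. It passed (adjusted p = 1.0e-05), but not with an estimated correlation (adjusted p = 0.26). Homologous recombination and Fanconi repair passed downward with 11 of 35 (adjusted p = 0.020) and colon epithelial genes upward with 2 of 11 (adjusted p = 0.037), CDH1, encoding E-cadherin, from 8.27 ± 0.60 to 13.5 ± 0.67 FPKM and EPCAM from 68.1 ± 4.6 to 84.7 ± 3.4. CPT-11 replicate 3 alone already had a repair median against untreated cells of -0.14, below the -0.13 to -0.08 of silenced libraries, and a mitosis median of -0.58 against -0.67 to -0.61. The mitosis median was -0.18 after the GC and length correction, in place of -0.27 (adjusted p = 1.7e-05). The repair and colon calls were lost with an estimated correlation (adjusted p = 0.40 and 0.27) and with the GC and length correction (adjusted p = 0.78 and 0.21). The colon call was also lost with only these groups in the fit and without CPT-11 replicate 1, where 0 lists passed upward. Without CPT-11 replicate 1, 4 lists passed downward in place of 2. Without CPT-11 replicate 2, 1 of the downward calls was lost.

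The innate immune genes were mixed in SHP2-silenced cells. Of 34 interferon-stimulated genes 3 rose and 7 fell, and the list did not pass (adjusted p = 0.18; median -0.07). IFIT2 fell from 15.1 ± 1.6 to 10.1 ± 0.75 FPKM, IFIT1 from 15.9 ± 1.1 to 12.1 ± 0.98 and IFIT3 from 13.1 ± 2.4 to 8.21 ± 0.38. TMEM173 rose from 8.89 ± 1.4 to 11.5 ± 0.36 FPKM (0.34 ± 0.09, adjusted p = 0.025), while TBK1, the kinase downstream of STING, fell from 16.7 ± 3.4 to 11.5 ± 0.85 (adjusted p = 0.030), a call that ended with the GC and length correction (from -0.49 ± 0.14 to -0.25 ± 0.08, adjusted p = 0.056) but passed with it when CPT-11 replicate 3 was also left out (adjusted p = 7.5e-03). The cGAS-STING list had 2 up and 2 down of 16 (adjusted p = 0.51). Directly against lovastatin-pretreated cells 0 of its members rose, 0 fell and the list did not pass (adjusted p = 0.86). TMEM173 measured 11.1 to 11.7 FPKM in silenced libraries, 10.1 to 11.2 in lovastatin libraries and 10.4 in CPT-11 replicate 3. Among NF-kB targets IL32 rose from 0.946 ± 0.25 to 3.52 ± 0.25 FPKM, whereas CXCL8 fell from 5.02 ± 0.79 to 2.04 ± 0.16 (list adjusted p = 0.94). CXCL10 (1.41 ± 0.60 FPKM) and CCL5 (1.33 ± 0.07) did not pass (adjusted p = 0.93 and 0.20). TOP1 fell from 100 ± 14 to 70.9 ± 1.2 FPKM (adjusted p = 6.3e-03) and PARP1 from 64.8 ± 4.2 to 56.3 ± 1.9 (adjusted p = 0.024). Lovastatin libraries also lay below the CPT-11 means, with TOP1 at 76.6 to 83.1 and PARP1 at 55.5 to 56.8 FPKM. CPT-11 replicate 3 itself had 84.5 FPKM of TOP1 and 60.5 of PARP1.

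Between SHP2-silenced cells and CPT-11 alone 3974 genes differed, 1807 higher and 2167 lower, with 93 at least 2-fold (74 up, 19 down). Scaling to library totals gave 2364 higher and 1639 lower. The count rested on single libraries: it was 7849 without CPT-11 replicate 3, 1007 and 1152 without replicates 1 and 2, and 1212, 1419 and 1978 without silenced replicates 1, 2 and 3. It was 451 with only these groups in the fit. Of 74 calls of named genes 40 ended in that fit, among them those of TMEM238, MRPL12, RAC3, TMEM141, TMEM173, TBK1, IFIT1, IFIT3, EPCAM, TOP1 and PARP1, and with the GC and length correction 17 ended and 1 more changed sign. The GC slopes of the groups differed, and RN7SL2 was higher in silenced cells (1255 ± 203 against 152 ± 215 FPKM), a difference in library content that runs with this comparison. With the GC and length correction 3223 genes differed, of which 1954 were among the 3974 (49.2%), and 5676 with it and without CPT-11 replicate 3. In the simulated draws from unchanged groups given below, up to 3633 genes were higher in both comparisons against CPT-11 (median 0). Counts of this order can thus arise without an effect of treatment, and calls per comparison were not kept.

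SHP2-silenced cells were also compared directly with lovastatin-pretreated cells, a comparison that does not use the CPT-11 libraries except for the shared spread. Library content differed here too, with 1255 ± 203 against 299 ± 64 FPKM of RN7SL2 and GC slopes of 0.12 against 0.05. Cholesterol synthesis and uptake was lower in silenced cells, 21 of 26 down and none up (23 adjusted over the list alone; median -0.96, adjusted p = 4.1e-38; adjusted p = 1.5e-04 with an estimated correlation). HMGCS1 was lower by -1.97 ± 0.07, INSIG1 by -1.74 ± 0.06 and MSMO1 by -1.53 ± 0.06. Fatty acid synthesis was lower in 8 of 14 (9 adjusted over the list alone; adjusted p = 8.2e-11; adjusted p = 1.5e-03 with an estimated correlation). The stress response was lower in 9 of 24 and higher in none (13 adjusted over the list alone; adjusted p = 2.6e-07; adjusted p = 0.042 with an estimated correlation), with SLC7A11, a cystine transporter gene, at 4.62 ± 0.39 against 8.74 ± 0.53 FPKM and CHAC1 at 3.26 ± 0.41 against 6.14 ± 0.33. Histones were lower in 3 of 9 (6 down and 1 up adjusted over the list alone; adjusted p = 1.0e-03; adjusted p = 0.042 with an estimated correlation).

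ERK pathway targets were lower in silenced than in lovastatin-pretreated cells, 9 down and 1 up of 26 (11 and 1 adjusted over the list alone; adjusted p = 2.6e-07), but not with an estimated correlation (adjusted p = 0.090). DUSP6 measured 21.2 ± 0.83 against 47.1 ± 1.2 FPKM, PHLDA1 27.4 ± 1.2 against 42.0 ± 0.12 and SPRY4, a feedback inhibitor of receptor signalling, was lower by -0.72 ± 0.06. Replication and E2F targets were higher in 10 of 37 (18 adjusted over the list alone; adjusted p = 1.2e-08; adjusted p = 0.060 with an estimated correlation), with MCM6 at 30.3 ± 1.0 against 19.3 ± 0.86 FPKM. NF-kB targets were lower in 6 of 21 and higher in 1 (9 and 2 adjusted over the list alone; adjusted p = 5.7e-03; adjusted p = 0.068 with an estimated correlation), with CXCL8 at 2.04 ± 0.16 against 6.41 ± 0.40 and CCL5 at 1.33 ± 0.07 against 2.91 ± 0.52. Prenylated GTPases and KLF factors (4 of 20 down, adjusted p = 0.030; adjusted p = 0.090 with an estimated correlation) and p53 targets (5 down, 1 up of 38, 7 and 3 adjusted over the list alone, adjusted p = 0.043; adjusted p = 0.12 with an estimated correlation) passed narrowly. Both were lost without lovastatin replicate 1 (adjusted p = 0.091 and 0.097), and the first without silenced replicate 3 (adjusted p = 0.051), the second without silenced replicate 1 or 2 (adjusted p = 0.072 and 0.069). The p53 list was also lost with a filter of at least 1 CPM, with only these groups in the fit and with scaling to library totals (adjusted p = 0.060, 0.060 and 0.059). Interferon-stimulated genes did not pass (5 of 34 down, 7 down and 1 up adjusted over the list alone, adjusted p = 0.073), with IFIT1 at 12.1 ± 0.98 against 18.5 ± 0.30 FPKM (adjusted p = 3.7e-04). This list passed without lovastatin replicate 2 or silenced replicate 2 (adjusted p = 0.031 and 0.032) and with only these groups in the fit (adjusted p = 0.048). Homologous recombination and Fanconi repair and mitosis passed upward after the GC and length correction (adjusted p = 2.2e-04 and 0.0497) and antigen presentation downward (adjusted p = 0.035). Without lovastatin replicate 3, 2 lists passed upward in place of 1.

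Other genes higher in silenced cells included MAGEB1, PROM2 and MAL2, by 1.65, 1.39 and 1.21, ARRDC4 at 16.3 ± 0.97 against 6.01 ± 0.21 FPKM, and CDH1 at 13.5 ± 0.67 against 7.73 ± 0.53 FPKM. CKMT1B was higher by 0.98, but shares reads with a near-identical copy. ADAM19 was lower, at 8.19 ± 0.83 against 21.9 ± 0.85 FPKM. In all 1235 genes differed, 466 higher and 769 lower, with 34 at least 2-fold (12 up, 22 down). Scaling to library totals moved the split to 625 higher and 672 lower. The count was 2438 with only these groups in the fit, 2195 with the GC and length correction and 598 to 731 without any 1 library of either group. Of 61 calls of named genes 1 ended with the GC and length correction and 10 to 13 without any 1 library of either group.

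Log2 changes of lovastatin and of SHP2 silencing, both against the same CPT-11 libraries, correlated across the 18062 genes with a Pearson r of 0.69 and a Spearman rho of 0.69, genes not being independent replicates. In 100 simulated draws the CPT-11, lovastatin and silenced groups all had the CPT-11 means. Their libraries, those of CPT-11 included, were redrawn from each group's own deviations, so the real CPT-11 libraries were not held fixed. The mean r was 0.67 and the median 0.75 (-0.01 to 0.98), and 60 draws were as high in r and 59 in rho. The correlation thus did not exceed what sharing a CPT-11 group gave in these draws. The draws held no treatment effects, which also change r, so this cannot decide whether a shared response was present. The covariance was 0.043 against a simulated mean of 0.019 (lowest -3.6e-05, highest 0.091), and 11 of the 100 draws were as high. There were 17 genes higher in both and 9 lower in both, against 7.10 and 1.56 from independent lists, and 5 that went opposite ways. Simulated draws had means of 134 and 128 genes higher and lower in both, medians of 0 and highest counts of 3633 and 3336, with 8 and 7 of 100 as high as the observed counts. Genes called in both were called in each comparison, so the size of a count against CPT-11 does not by itself show an effect. The 3 shared libraries cannot be split with 2 in each part, so the counts shared by both may come from them.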

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

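GC and length correction, scaling to library totals or by a trimmed mean of M-values, and voom on the recovered reads were chosen after the data were seen. Apart from voom, no test on counts was run. List tests were not repeated without a filter, with a pseudocount of 0.1, without the 20 most counted genes or with voom. A result counts here as reversed where its sign changed and it passed its test with or without the alternative. A minimum of 2-fold left 121 genes for CPT-11 against untreated, 17 for lovastatin against CPT-11, 93 for SHP2 silencing against CPT-11 and 34 for SHP2 silencing against lovastatin, in place of 2989, 84, 3974 and 1235. With only the groups compared in the fit the counts were 1154, 36, 451 and 2438. Without a filter the count for silencing against CPT-11 was 1750, and with voom that of lovastatin was 141. With the GC and length correction counts were 4560 for CPT-11 against untreated, 335 for lovastatin against CPT-11 and 2195 for silencing against lovastatin. With this correction and without CPT-11 replicate 3 they were 4866, 3066 and 2781, and 5676 for silencing against CPT-11, where the correction alone gave 3223. PTPN11 passed in CPT-11 against untreated in both of these settings, with changes of -0.176 and -0.190. The cause of these moves was not tested.

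Leave-one-out counts were 1931 (without untreated replicate 2) to 4420 (without CPT-11 replicate 3) for CPT-11 against untreated, and 41 (without lovastatin replicate 1) to 5455 (without CPT-11 replicate 3) for lovastatin against CPT-11. They were 1007 (without CPT-11 replicate 1) to 7849 (without CPT-11 replicate 3) for silencing against CPT-11, and 598 (without silenced replicate 2) to 731 (without lovastatin replicate 1) for silencing against lovastatin. The counts of 5455 and 7849 compare libraries that were apart in GC slope and RN7SL2 as well as in treatment. PTPN11 kept its call in silencing against both groups in all settings run.

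Replicate numbers did not pair the samples: 2 of 18 same-number pairs had a correlation above 0.1. With the number as a block the counts were 2275 for CPT-11 against untreated, 46 for lovastatin against CPT-11 (46 higher, 0 lower), 2356 for silencing against CPT-11 and 767 for silencing against lovastatin, and genes higher and lower in both lovastatin and silencing were 8 and 0. The block ended 1 list call, that of p53 targets in silencing against lovastatin (adjusted p = 0.060).

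Of 22 lists, 11, 10, 3 and 9 passed in the 4 comparisons, and 4, 5, 0 and 4 passed camera with an estimated correlation. By limma's fry 12 passed in silencing against CPT-11. With the GC and length correction the change of PDGFRB with silencing, 0.13 before, was reversed to -0.019, and to -0.077 without CPT-11 replicate 3. BAD, 0.53 before, was reversed to -0.049 in the latter setting. None of these reversed values passed.

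Genes higher and lower in both lovastatin and silencing were 17 and 9. With the GC and length correction there were 40 and 70 and the Pearson r was 0.559. With this correction and without CPT-11 replicate 3 there were 1125 and 997. With a filter of at least 1 CPM 18 were lower in both. Leave-one-out gave 3 (without CPT-11 replicate 2) to 2315 (without CPT-11 replicate 3) higher, 0 (without CPT-11 replicate 1) to 2163 (without CPT-11 replicate 3) lower, and a Pearson r of 0.564 (without CPT-11 replicate 2) to 0.826 (without CPT-11 replicate 3). The values without CPT-11 replicate 3 rest on CPT-11 libraries apart from both groups in GC slope and RN7SL2.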

Other observations

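The tests of CPT-11 replicate 3, of GC content on the interferon-stimulated genes and of epithelial and mesenchymal genes were chosen after the result was seen. Epithelial and mesenchymal genes differed in opposite directions between SHP2-silenced cells and CPT-11 alone. Lists of both kinds, written after the named genes had been seen, were tested in silencing against CPT-11 alone. Left out were members named by the rule in the silencing comparisons, and AP1M2, S100A14 and VIM. Other members of the fixed lists stayed in, such as KRT8 and ACTA2, the latter named above for CPT-11 against untreated cells. Of 40 epithelial genes 27 rose and 0 fell, with a median log2 change of 0.43 (camera, adjusted p = 3.8e-13; adjusted p = 0.013 with an estimated correlation). CLDN7, a tight junction gene, rose from 20.4 to 44.6 FPKM and GRHL2, an epithelial transcription factor gene, from 2.39 to 4.74. Of 32 mesenchymal genes 10 fell and 1 rose, with a median of -0.09 (adjusted p = 0.011; adjusted p = 0.020 with an estimated correlation). ZEB1, a repressor of epithelial genes, fell from 1.74 to 0.526 FPKM. CLDN7, GRHL2 and ZEB1 were named after their values were seen. The medians differed by 0.523. With all members 34 of 48 epithelial genes rose and 1 fell, EHF, by 1.17, and 16 of 40 mesenchymal genes fell and 3 rose, COL1A1 and PDGFRB among them. After the GC and length correction both passed (adjusted p = 7.1e-12 and 2.1e-04), with 27 epithelial genes up and 3 down and a median of 0.30. Without CPT-11 replicate 3 only the epithelial list did, with 29 up and 3 down (adjusted p = 3.4e-10 and 0.071). These lists were not tested against the lovastatin group. In that comparison the fixed list of colon epithelial genes did not pass, with 2 of 11 up and 0 down (median -0.009, adjusted p = 0.43). A more epithelial state of the silenced cells may explain the differences from CPT-11 alone, as a hypothesis found and tested on the same data. The vector and derived cells remain untested.

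Lovastatin in the SHP2-silenced cells, as their treatment label has it, was tested with the cholesterol list. Its median was 0.0973 in silenced cells against CPT-11 alone, below 0.534, which is 0.5 of the lovastatin median, and the groups differed in the list (adjusted p = 4.1e-38). The list did not pass in silenced cells against CPT-11 alone (adjusted p = 0.17), but passed upward with the GC and length correction, with a median of 0.079 (adjusted p = 0.011), and with it and without CPT-11 replicate 3, with 0.092 (adjusted p = 6.1e-03). These values argue against a response of the size seen in the lovastatin group; a smaller response, or a treatment without one at 24 h, stays open.

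CPT-11 replicate 3 differed from its group by a root mean square of 0.330 (log2), and by 0.257 after the GC and length correction, against at most 0.195 in the other groups (SD of those 9 libraries 0.0129). GC and length therefore did not account for all of it. A lovastatin library under the wrong label would have raised the cholesterol list by about 1.13, and the rise was 0.0934. An untreated library would have lacked the p53 response, which was 1.07 against 0.989 in replicates 1 and 2. A difference of handling, culture or library preparation stays open, since the labels give no batch.

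The rise of interferon-stimulated genes with CPT-11, a median of 0.391, was 0.397 after the GC and length correction. The highest median of 10000 random lists of matched expression was 0.138. With a single CPT-11 library left out in turn, the lowest median was 0.359. These values argue against GC content, low expression or a single CPT-11 library as its whole cause. Which signal drove the rise was not tested, and CGAS and IFNB1 had too few reads to test.

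The 6 libraries of each comparison make 10 splits of 3 against 3, too few for a share under 0.05; in each, 1 split (the real one) gave as many genes. The real and highest other counts were 2989 and 564 for CPT-11 against untreated, 84 and 60 for lovastatin against CPT-11, 3974 and 0 for silencing against CPT-11, and 1235 and 1 for silencing against lovastatin. The other split with 564 genes put CPT-11 replicate 3 with untreated replicates 1 and 2, and that with 60 put lovastatin replicate 3 with CPT-11 replicates 1 and 2.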
